A study of Xenopus laevis with 12 samples.

How the data were processed

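The series profiles ribosome-bound RNA of retinal ganglion cells of adult Xenopus laevis after crush of the optic nerve. Per the labels, transgenic frogs carried an EGFP-tagged rpl10a under an islet2b promoter, and RNA was recovered from retinas with antibodies against EGFP (TRAP). Per the extraction protocol, lens and pigment epithelium were removed, and each TRAP library was pooled from 3 independent biological replicates, so that every condition is 1 library. The 12 libraries are 1 of total retina RNA, 1 of TRAP RNA from unoperated frogs (naive), 2 from sham-operated frogs at day 1 (left and right eye), and 4 each from the crushed right eye and the contralateral left eye at days 1, 3, 7 and 11. The labels place the crush in the right eye, and 1 sentence of the design text names the left. The labels were followed. On the first principal component the libraries labelled as crushed at days 3, 7 and 11 lay apart from every other TRAP library, and that of day 1 did not. Such a separation does not show which eye was crushed.

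Per the submitters' processing notes, Trimmomatic 0.33, Bowtie2 2.2.5 and RSEM 1.2.21 were used. Genome build and annotation are not given in the sources used here. The authors' tables hold, per the file headers, an expected count (a read count estimated by RSEM, with 57.9% of values whole within 0.001), a TPM value, and a gene model length. The deposited TPM values were read to check the tables and enter no result. Expected counts were rounded to whole numbers, which moved no library total by more than 0.000797%. Each table has 45099 gene models. Of these, 17324 carry a gene symbol, and 11989 of the symbols are also in the gene table of assembly Xenopus_laevis_v10.1, which served for names only. The other 27775 carry a model name. The .L and .S copies of a gene, which descend from the ancestral genome duplication, were treated as separate genes, and reads of near-identical copies can be shared between them. List genes with no matching symbol, gap43, rho, isl2 and gapdh among them, could not be looked up by name and are missing from their lists. Models without a symbol were kept in the tests over all genes. The rpl10a.S model is the 1 rpl10a copy with a symbol, and reads from the transgene may be counted in it.

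Counts were 24228825 in total retina, 47326216 in naive TRAP, and 59265354 and 16978152 in sham left and right. The contralateral eye had 55517533, 34978173, 16820571 and 43576308 at days 1, 3, 7 and 11, and the crushed eye 49796016, 22615151, 63299998 and 46385324. The 10 most counted genes took 3.04% to 9.42% of a library.

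The crush effect shared by the days was tested with the quasi-likelihood F test of edgeR 4.0.16 (robust, TMM scaling, filterByExpr by eye) in R 4.3.3, on 4 crush against 4 contralateral libraries with day as a block. Both libraries of a day come from the eyes of the same frogs, per the protocol. Deviations of the libraries of 1 day from their group means had correlations across genes of 0.0834, 0.0595, 0.0465 and 0.0430 at days 1, 3, 7 and 11. A second edgeR test asked whether the log2 ratio of crush to contralateral changed with log2 of the day, with 2 residual degrees of freedom. Slopes are log2 units per doubling of the day, and a gene is said to rise or fall with day when this slope passed. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05, and errors are standard errors of the fit. The 34 gene lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with an estimated correlation, and with fry. With an estimated correlation, camera also tests on the residual degrees of freedom of the fit, which are few here. Single days, sham and naive TRAP against total retina are 1 library against 1 and were not tested: they are given as log2 ratios of TMM-scaled CPM (counts scaled by library size) with a prior count of 2. Each list median was placed among 10000 random lists matched on mean expression in 50 bins. Members of a random list were drawn independently and could include the list's own genes, so the placement takes no account of correlation within a list. Ratios against 0 counts are given as "at least" values from a limit of 3 counts. Intervals of folds are 95% intervals for counting error only and cover no difference between frogs.

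The tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined, except the tests of lists for a slope with day. Those list slope tests were not among the planned tests, and their adjusted p-values are exploratory. For the 4-day comparison the rule takes the 10 highest and lowest fold changes past the threshold with 1 direction in all 4 pairs, a symbol and 100 counts, filled with the smallest p-values where fewer pass. For each day it takes the 4 highest and lowest ratios with a symbol, 200 counts over the pair and an absolute sham log2 ratio under 1, for sham the 4 highest and lowest, for TRAP against total retina the 10 highest and lowest, and for the day slope the 5 rising and 5 falling genes of smallest p. From each list described it takes the members called in the 4-day comparison and 2 to 4 members of highest mean count. Further list members named here were chosen after their values were seen, and some members that the rule takes are not reported here.

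Fits were tested on simulated data with 26004 genes, of which 200 were changed. With the spread of the 8 libraries, 75% of genes changed 8-fold and 3% of those changed 2-fold were called in the 4-day comparison, and 1.27% of the calls were false. With the spread of the 7 uninjured TRAP libraries these shares were 93%, 71% and 5.75%, and for the slope 67%, 11% and 3.70%. Camera called 10 of 10 raised lists and 0 of 10 unchanged ones. These genes were simulated independently with the spread of the uninjured libraries, so the result does not cover lists of correlated genes. In the data the estimated correlation within a list ranged from -0.30 (oligodendrocyte and Schwann cell markers) to 0.82 (mitochondrial respiratory chain), with 0.70 for ribosomal proteins.

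Alternatives were the model without day, RLE factors, DESeq2 1.42.0, limma-voom, no expression filter and a stricter one, all 7 uninjured TRAP libraries as controls, each day left out in turn, .L and .S copies summed, a 2-fold minimum, a slope on day, an estimated correlation and fry for lists, and, for single pairs, total counts, a prior count of 0.5, other count minimums and a 4-fold limit. Libraries thinned to the smallest total, RLE factors for list medians, settings for the slope that go beyond the planned ones, and families of genes that share a symbol stem were added after the data had been seen. Planned pseudocounts for TPM or FPKM values were not run, since the tables hold counts. Total counts in place of TMM moved the median log2 ratio of genes by -0.29 at day 7, -0.38 at day 11 and -0.11 for naive TRAP against total retina. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.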

Results

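TRAP RNA of unoperated frogs carried the transcripts of retinal ganglion cells and was poor in those of the other retinal cells. The 42 retinal ganglion cell markers had a median log2 ratio of 3.29 over total retina (1 library each). sncg.L was at 3.99, pou4f2.L at 4.21, nefh.L at 3.28, rbpms2.L at 2.81 and thy1.L at 3.19. These encode gamma-synuclein, a POU-domain transcription factor, the heavy neurofilament chain, an RNA-binding protein and a surface glycoprotein. Photoreceptor markers (46) had a median of -3.88, with the phototransduction genes gnat1.L at -4.43 and pde6h.S at -4.37. Medians were -3.55 for bipolar cells, -2.60 for amacrine and horizontal cells, -2.70 for Mueller glia and astrocytes and -2.28 for pigment epithelium. They were -1.51 for leukocytes and microglia, -1.68 for oligodendrocytes and Schwann cells and -2.52 for endothelial and blood cells. The 15 lens and cornea markers, at 2.26, were the 1 marker list besides that of ganglion cells above 0. Their counts were few: cryba1.L, the most abundant, averaged 9.85 CPM over the 8 crush and contralateral libraries.

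Among 19677 genes with 200 counts over the pair, 3802 were over 2-fold higher and 3857 over 2-fold lower in naive TRAP than in total retina. Of these, 3727 and 3803 lay on the same side of total retina in all 7 uninjured TRAP libraries, and 2645 and 3396 in all 11 TRAP libraries, the crushed eyes included. Naive TRAP, by which the genes were picked, is among these libraries, and all are set against the same total retina library. The counts therefore do not cover error in that library. The highest ratios were those of klhl10-like.1 (108-fold, counting interval from 56.8), gng7.S (49.9-fold), tbr1.L (33.6-fold, a T-box transcription factor), exoc3l4.L (34.0-fold) and rag2.S (34.5-fold). They were followed by grp.L (29.7-fold, gastrin-releasing peptide), ppp1r1c-like.S (26.5-fold) and kctd8.S (24.8-fold). myeov2.L was at least 72.7-fold and rflcii.1 at least 38.5-fold higher. The lowest were nyx.L (at least 252-fold lower, the bipolar cell protein nyctalopin), acvr1c.S (at least 148-fold), fhdc1.S (at least 142-fold) and tk1.L (at least 126-fold). Genes with 1 count in naive TRAP were ntf3.S (647-fold, interval from 115), epas1.S (493-fold, from 87.7), sgk3.S (485-fold, from 86.4), anxa1-like.1.S (467-fold, from 83.1), mlana-like.S (458-fold, from 81.5) and s1pr1.S (386-fold, from 68.5).

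The profiles of sham-operated eyes at day 1, and of eyes contralateral to a crush, lay close to that of naive eyes. Over 16096 genes, the contralateral libraries had 78, 79, 87 and 96 genes over 2-fold above naive TRAP at days 1, 3, 7 and 11, and 66, 56, 84 and 70 below. Sham left and right had 85 and 69 above and 92 and 78 below. Between the sham eyes, 85 genes were over 2-fold higher and 167 lower on the right, of 18542, with 3 over 2-fold at 1000 counts or more. The highest were impg2.L (3.05-fold) and slc24a1-like.S (2.69-fold), both of photoreceptors, with tll1-like.1.1 (2.87-fold) and dlg2-like.2.S (2.76-fold). The lowest were chsy3.L (9.17-fold lower, from 7 and 224 counts), nuak2.L (7.02-fold), nat8l.S (5.52-fold) and fam214b.S (4.50-fold). Photoreceptor markers had a median log2 ratio of 0.50 between the sham eyes, against -0.04 for retinal ganglion cell markers.

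**Figure D1:**
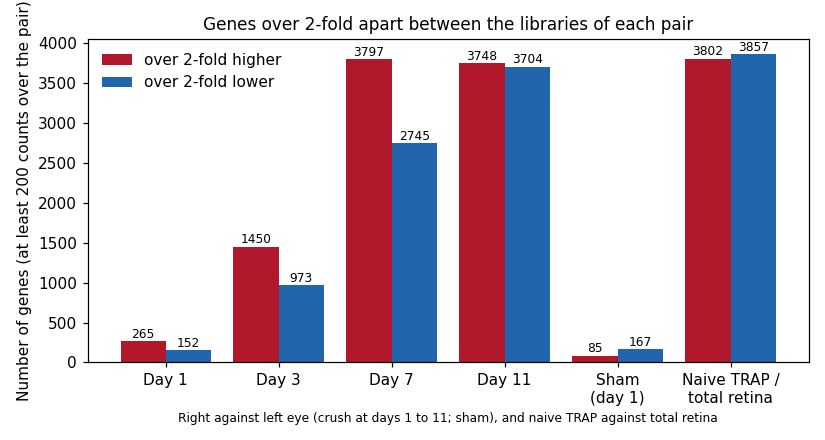
Number of genes over 2-fold higher (red) or lower (blue) between the libraries of each pair: right against left eye after crush at days 1, 3, 7 and 11 and after sham surgery, and naive TRAP against total retina. The counts at day 11 were 3748 and 3704, against 85 and 167 for sham, and with total counts in place of TMM they were 2412 and 5337 at day 11 and 2750 and 3788 at day 7, where TMM gave 3797 and 2745.

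Few genes differed between the eyes at day 1 after crush and many at day 7. Genes over 2-fold apart between the eyes numbered 417 of 20006 at day 1 (265 higher, 152 lower), 2423 of 17726 at day 3 (1450 and 973), 6542 of 18384 at day 7 (3797 and 2745) and 7452 of 19170 at day 11 (3748 and 3704), against 252 for sham. The split between higher and lower depended on scaling: with total counts it was 2750 and 3788 at day 7 and 2412 and 5337 at day 11. Log2 ratios of days 7 and 11 correlated at r = 0.733 across genes, those of days 3 and 7 at 0.417 and those of days 3 and 11 at 0.359. With day 1 the highest was 0.0555 (Spearman 0.0922), and genes are not independent replicates. On the first principal component, with 50.4% of the variance, the crush libraries of days 3, 7 and 11 lay at 46.0, 168 and 193. That of day 1 lay at -47.9, within the range of the uninjured libraries (-57.5 to -44.0).

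Over the 4 days together, 10 genes passed in edgeR, all 10 higher after crush (26004 genes tested, n = 4 pairs). Of the 10, 8 had the same direction in all 4 pairs. fosl1.L, an AP-1 subunit, was higher by 7.79 ± 0.71 on the log2 scale (adjusted p = 0.0418). socs3.S, a feedback inhibitor of cytokine signalling, was higher by 6.53 ± 0.37 (adjusted p = 0.00619), from 2.23 CPM in the contralateral eye to 136.8 CPM in the crushed eye at day 11. Filamin C, flnc.L, was higher by 6.40 ± 0.37 (adjusted p = 0.00619), the kelch protein gene klhl40.S by 6.40 ± 0.60 (adjusted p = 0.0418) and the transporter gene slc35g1.L by 4.26 ± 0.38 (adjusted p = 0.0399), each in 4 of 4 pairs. The other 5 fall outside the rule for named genes and were singled out after their values were seen: eda2r-like.1 (6.05, adjusted p = 0.0187), LOC100492639-like.L (7.15, adjusted p = 0.00619), Xelaev18005363m (7.11, adjusted p = 0.0418), Xelaev18046356m (6.67, adjusted p = 0.0206) and Xetrov90019643m.L (4.92, adjusted p = 0.00630).

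Next by p-value, and short of the threshold, were higher values of herc6.L (3.96, adjusted p = 0.0773), creb5-like.L (6.20, adjusted p = 0.0773), the LIM-domain gene fhl3.L (5.11, adjusted p = 0.118), flnc.S (5.01, adjusted p = 0.136) and hpd-like.2.L (5.40, adjusted p = 0.141). No gene was lower past the threshold in edgeR, against 1467 lower in DESeq2. In edgeR 5395 genes of either direction had an unadjusted p under 0.05. The lower genes of smallest p all had an adjusted p of 0.223: dbf4.L at -1.70, chek1.L (checkpoint kinase) at -1.57, eomes.S (a T-box factor of a ganglion cell subset) at -1.52, mtfp1.L at -1.48, and irx3.S at -1.38. The others were ttc28-like.S at -1.33, mycbp.1 at -1.19, ddah2.S at -0.97, pmel-like.S at -1.76 and asb5.S at -2.22.

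The 4-day count rests on the model and on day 1, when the effect was small. Without the day block edgeR called 0 genes (5450 at an unadjusted p under 0.05). With the block, limma-voom called 12, with 6 of the 10 among them, and DESeq2 3127 (1660 higher, 1467 lower), with all 10 among them. Without day 1 edgeR called 2678 genes (1611 higher, 1067 lower), the 10 included. Without day 3 it called 4, without day 7 it called 0 and without day 11 it called 2. Among the named genes, fosl1.L and slc35g1.L missed the threshold without any 1 of days 3, 7 and 11, socs3.S and klhl40.S without day 3 or 7, and flnc.L without day 7. klhl40.S was not among the genes tested without day 11.

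The crush effect changed with day for 3296 genes in edgeR, with 1515 rising and 1781 falling (7145 at an unadjusted p under 0.05). None of them is among the 10 genes above. anxa2.S, annexin A2, rose most clearly, by 1.56 ± 0.11 per doubling of the day (adjusted p = 0.00169). It went from 23.1 CPM at day 1 to 1421 CPM at day 11 in the crushed eye against 36.1 CPM in the contralateral eye. phyhip.L rose by 1.28 ± 0.11 and the cysteinyl-tRNA synthetase gene cars.S by 1.22 ± 0.11 (adjusted p = 0.00279 each), together with the models Xelaev18016849m (1.49) and Xelaev18024621m (1.32). pou4f3.L, a POU-domain factor of retinal ganglion cells, fell by 1.86 ± 0.18 (adjusted p = 0.00279). It went from 75.4 to 1.27 CPM in the crushed eye against 87.9 CPM in the contralateral eye at day 11. The copine gene cpne7.S fell by 1.69 ± 0.17, the AMPA receptor-associated gene prrt1.L by 1.16 ± 0.12 (adjusted p = 0.00311), MGC145303.L by 1.71 ± 0.18 and Xelaev18036861m by 1.67 ± 0.17. Leaving out 1 day moved the count to 3603 (day 1), 5163 (day 3), 1527 (day 7) and 1233 (day 11). Of 235 members of the gene lists called for the slope, 137, 234, 99 and 69 were still called without day 1, 3, 7 and 11, and 37 without each day in turn.

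**Figure D2:**
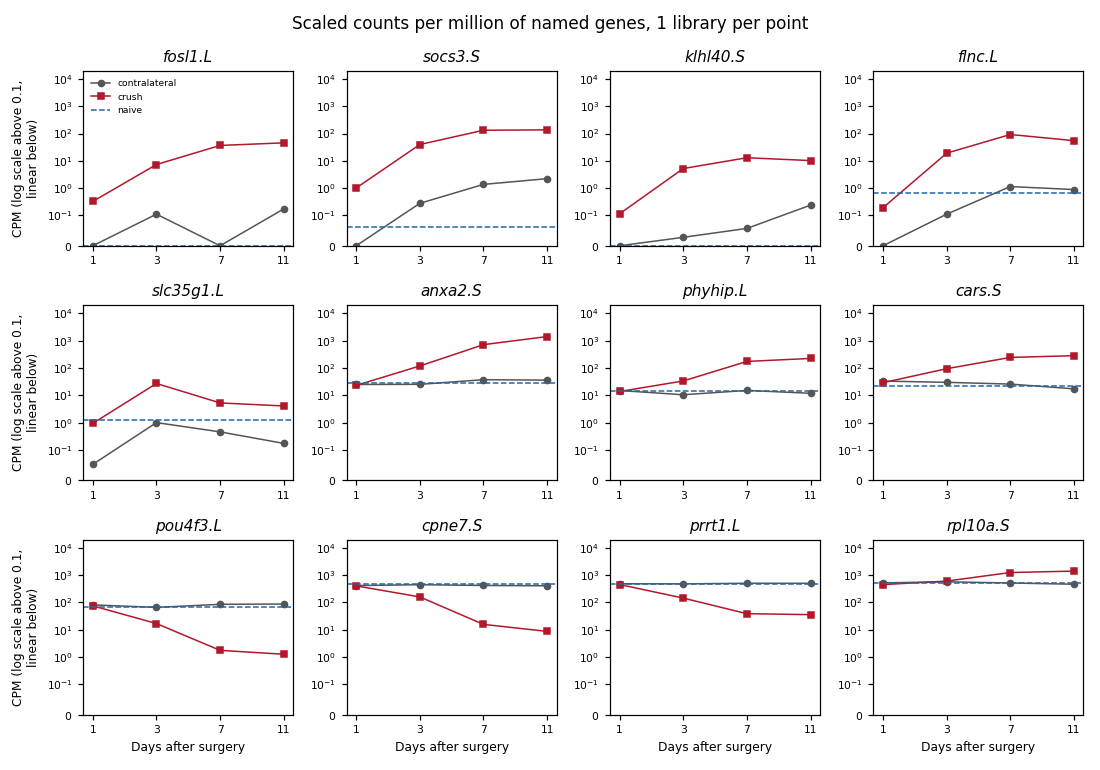
TMM-scaled CPM (log scale above 0.1, linear below) of 12 genes against days after surgery in the crushed (red) and contralateral (grey) eye, 1 library per point, with naive TRAP dashed. anxa2.S reached 1421 CPM and pou4f3.L 1.27 CPM in the crushed eye at day 11, and rpl10a.S, which may include transgene reads, 1413 CPM against 466 CPM.

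Retinal ganglion cell markers fell. Of 42 members 26 fell and 1 rose with day (29 and 2 adjusted over the list alone). The other 15 passed in neither direction. The list fell in camera (adjusted p = 2.11e-09; adjusted p = 0.628 with an estimated correlation). Medians were -0.04, -0.83, -2.09 and -2.00 at days 1, 3, 7 and 11, the last 3 below each of the 10000 random lists, against -0.04 for sham. An extreme placement is not specific to crush: between the sham eyes photoreceptor markers lay at percentile 100 and KLF factors at percentile 0. The ganglion cell list lay there at percentile 18.5. sncg.L fell by 1.52 ± 0.23 per doubling of the day (adjusted p = 0.00847), rbpms2.L by 1.44 ± 0.25 (0.0155) and pou4f2.L by 1.25 ± 0.16 (0.00354). nefh.L fell by 1.15 ± 0.20 (0.0105) and the internexin copy ina.1 by 0.57 (0.0189). The exception was tubb3.S, neuronal beta-tubulin, which rose by 0.72 ± 0.15 (0.0135). The more abundant ina.S (-0.72 at day 11, adjusted p of the slope 0.173), thy1.L (-0.39, 0.305), nefl.L (-1.03, 0.110) and nefm.L (1.09, 0.412) did not pass. For the 4 days together the list was lower (camera adjusted p = 4.40e-08; 0.629 with an estimated correlation). 0 members were called over all genes or over the list alone, and 22 were lower without day 1. Leaving out day 1 lost the slope calls of rbpms2.L (0.193), nefh.L (0.0859) and ina.1 (0.0559), day 7 those of ina.1 (0.0629), day 11 those of ina.1 (0.0566) and tubb3.S (0.184). Those of sncg.L and pou4f2.L held with any 1 day left out.

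Genes of synaptic release, ion channels and axon guidance fell in the same period. Synaptic release genes (17) had 8 fallen and 0 risen (10 and 0 adjusted over the list alone; camera adjusted p = 0.000777; adjusted p = 0.628 with an estimated correlation). Medians were -1.12 and -1.42 at days 7 and 11. cplx1.1 (complexin) fell by 1.17 ± 0.14 (adjusted p = 0.00311), snap25.S by 0.85 ± 0.15 (0.00933) and nsf.L by 0.54 ± 0.11 (0.0149). snap25.L, at -1.42 on day 11, missed the threshold (0.0562). Neuronal ion channels and pumps (37) had 10 fallen and 1 risen (11 and 1 adjusted over the list alone; camera adjusted p = 0.0152; adjusted p = 0.628 with an estimated correlation). The sodium channel subunit scn2b.L fell by 1.65 ± 0.31 (0.0227), the potassium channel kcna1.L by 1.02 ± 0.13 (0.00375) and the sodium pump subunit atp1b1.S by 0.50 (0.0229). Axon guidance and adhesion genes (38) had 8 fallen and 1 risen (14 and 1 adjusted over the list alone; camera adjusted p = 0.00251; adjusted p = 0.725 with an estimated correlation). Slopes were -1.04 ± 0.19 for sema3d.S (adjusted p = 0.00966), -0.70 for plxnb1.L (0.0136), -0.74 for plxnb1.S (0.0200) and 0.50 for robo3.L (0.0461). The abundant ncam1.L had a day 11 ratio of 0.04. Over the 4 days synaptic release was lower (camera adjusted p = 0.0141, 0.0602 without day 11, adjusted p = 0.629 with an estimated correlation). Channels had an adjusted p of 0.0667 (0.0439 without day 1 and 0.0360 without day 3) and guidance 0.116 (0.0262 without day 3). Slope calls were lost without day 1 for nsf.L (0.0502) and robo3.L (0.156), without day 7 for nsf.L (0.0617), scn2b.L (0.141), atp1b1.S (0.0853) and robo3.L (0.189), without day 11 for snap25.S (0.0768), nsf.L (0.0802), scn2b.L (0.240), atp1b1.S (0.218), sema3d.S (0.0587), plxnb1.S (0.0848) and robo3.L (0.0653). Those of cplx1.1, kcna1.L and plxnb1.L held with any 1 day left out.

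No marker list of other retinal cells rose with day. Photoreceptor markers fell with day (camera adjusted p = 5.50e-06; adjusted p = 0.628 with an estimated correlation), with 4 of 46 members fallen (impg2.S, impg2.L, gucy2f.S and pde6a.S; 0 adjusted over the list alone). Medians were 0.21, -0.05, -0.47 and -0.55 after crush, and 0.50 between the sham eyes. Over the 4 days they were lower (adjusted p = 0.0372; adjusted p = 0.774 with an estimated correlation), a call that was lost without day 7 (0.277) or day 11 (0.503) and with copies summed (0.0625). Bipolar cell markers fell (adjusted p = 0.0259, and 0.165 without day 1; adjusted p = 0.628 with an estimated correlation). 2 of 15 members fell, also over the list alone: gpr179.L fell by 0.79 ± 0.14 (0.00898) and gpr179.S by 0.67 ± 0.16 (0.0237). Their 4-day value was 0.0505 (0.0288 without day 1, 0.0358 without day 3). Amacrine and horizontal cell markers (20 members, 0 called, also over the list alone) had an adjusted p of 0.131 and a day 11 median of -0.39. Mueller glia and astrocyte markers (25) had a day 11 median of -0.06 and an adjusted p of 0.879. vim.L (vimentin) rose by 1.36 ± 0.22 (adjusted p = 0.00975) and ca2.L fell by 0.44 (0.0408), with 1 risen and 0 fallen adjusted over the list alone. vim.L reached 404 CPM at day 11 in the crushed eye against 11.0 CPM. cd44.S had log2 ratios of 3.36, 6.85 and 3.28 at days 3, 7 and 11 (adjusted p = 0.0251 without day 1, 0.175 for the slope). Leaving out day 1 lost the slope calls of impg2.S (0.134), impg2.L (0.0743), gucy2f.S (0.141), pde6a.S (0.0746), gpr179.S (0.171) and ca2.L (0.0602), day 7 those of impg2.S (0.0651), impg2.L (0.0568), gucy2f.S (0.0851), pde6a.S (0.183), gpr179.S (0.0575) and ca2.L (0.190), day 11 those of impg2.S (0.139), impg2.L (0.347), gucy2f.S (0.183), pde6a.S (0.400), vim.L (0.0580) and ca2.L (0.168). That of gpr179.L held with any 1 day left out.

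Pigment epithelium markers (7, with 0 called) were lower over the 4 days (camera adjusted p = 0.0101; adjusted p = 0.629 with an estimated correlation). Medians were -0.70, -0.42, -1.13 and -1.18 after crush and -0.44 for sham, with a slope adjusted p of 0.326. Among oligodendrocyte and Schwann cell markers, mpz.L, myelin protein zero, which averaged 482 CPM, fell by 0.95 ± 0.13 (adjusted p = 0.00407), as 1 of 4 members over all genes and over the list alone. The list had an adjusted p of 0.110 for the slope and 0.0525 over the 4 days (0.0411 without the day block). Leukocyte and microglia markers (11) had medians of 0.55, -0.39, -0.46 and -0.14 and a slope adjusted p of 0.506. Its 2 risen members, also over the list alone, were the copies of the chemokine receptor gene cxcr4, with cxcr4.S at 1.00 ± 0.17 (0.00803) and cxcr4.L at 1.02 ± 0.20 (0.0113). Endothelial and blood cell markers (15, 0 called, 0 over the list alone) had medians of 0.53, 0.84, 0.23 and -0.30 (below 0 at day 7 with total counts), a slope adjusted p of 0.428 and a 4-day value of 0.204 (higher at 0.0198 without day 11). Lens and cornea markers (15, 0 called, 0 over the list alone) had a slope adjusted p of 0.961 (rising at 0.0386 without day 1). Slope calls were lost without day 11 for cxcr4.S (0.101) and cxcr4.L (0.149). That of mpz.L held with any 1 day left out.

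Ribosomal protein and proteasome genes rose with day. Of 58 cytosolic ribosomal protein genes 53 rose and 0 fell (57 and 0 adjusted over the list alone; camera adjusted p = 5.31e-21; adjusted p = 0.628 with an estimated correlation). Medians were 0.03, 0.54, 1.53 and 1.59 at days 1, 3, 7 and 11 and -0.04 for sham. The abundant rpl3.L rose by 0.67 ± 0.12 (adjusted p = 0.00803) and rps3a.S by 0.49 (0.0189). rpl10a.S, whose counts can include the transgene, rose by 0.55 ± 0.12 (0.0160). Of 51 proteasome genes 34 rose and 0 fell (48 and 0 adjusted over the list alone; camera adjusted p = 2.21e-15; adjusted p = 0.628 with an estimated correlation). Medians were -0.13, -0.01, 1.29 and 1.43. psmc6.L rose by 0.60 ± 0.12 (0.0147). psmc5.L (1.05 at day 11, 0.0658) and psmd3.L (0.79, 0.178) missed the threshold. In the 4-day comparison ribosomal protein genes (camera adjusted p = 8.18e-16) and proteasome genes (2.22e-07) were higher (adjusted p = 0.629 with an estimated correlation for each). Leaving out day 7 lost the slope calls of rps3a.S (0.0811), rpl10a.S (0.0519) and psmc6.L (0.0511), day 11 those of rps3a.S (0.141), rpl10a.S (0.177) and psmc6.L (0.0890). That of rpl3.L held with any 1 day left out.

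Integrated stress response and amino acid supply genes (35) were higher after crush, with medians of 0.07, 2.26, 2.05 and 2.17 at days 1, 3, 7 and 11. On the last 3 days these genes lay above each of the 10000 random lists, a placement that some other lists reached between the sham eyes. Their own sham median was -0.06. They were higher over the 4 days (camera adjusted p = 6.57e-14; adjusted p = 0.629 with an estimated correlation). 0 members were called over all genes, with 29 higher adjusted over the list alone and 29 higher over all genes without day 1. asns.L (asparagine synthetase) had log2 ratios of 3.92, 4.22 and 5.00 at days 3, 7 and 11 (adjusted p = 0.00245 without day 1), ddit3.L (CHOP) 5.05, 4.39 and 4.27 (0.00194) and the arginine transporter slc7a3.L 3.98, 4.13 and 4.32 (0.00172). Values for cebpg.L were 3.20, 2.97 and 3.23 (0.00255), for the abundant atf4.S 1.91, 1.68 and 1.16 (0.0304) and for atf4.L 1.12, 1.10 and 0.72 (0.0662). With day, 10 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 1.82e-07; adjusted p = 0.725 with an estimated correlation). asns.L rose by 1.39 ± 0.24 (0.0115), gars.L by 0.74 ± 0.13 (0.00966) and sars.L by 0.71 ± 0.14 (0.0117). Without day 1 the list's direction reversed (adjusted p = 0.331). Slope calls were lost without day 1 for asns.L (0.0801), slc7a3.L (0.634), cebpg.L (0.956), gars.L (0.318) and sars.L (0.397), without day 7 for slc7a3.L (0.0854) and cebpg.L (0.140), without day 11 for cebpg.L (0.0716).

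The unfolded protein response and cytosolic chaperones rose with day. Endoplasmic reticulum unfolded protein response genes (24) had 7 risen and 0 fallen (7 and 0 adjusted over the list alone; camera adjusted p = 0.000242; adjusted p = 0.628 with an estimated correlation). Medians were 0.31, 0.78 and 0.79 at days 3, 7 and 11. hspa5.L (BiP) rose by 0.77 ± 0.11 (adjusted p = 0.00445), hspa5.S by 0.45 (0.0222) and xbp1.S by 0.75 ± 0.17 (0.0212). p4hb.L, the most abundant, had 0.66 at day 11 (0.212). Cytosolic chaperones (26) had 9 risen and 1 fallen (14 and 1 adjusted over the list alone; camera adjusted p = 6.05e-06; adjusted p = 0.628 with an estimated correlation). cryab.S and cryab.L, alpha-B crystallin, rose by 1.59 ± 0.23 (0.00470) and 1.40 ± 0.16 (0.00311), while hspa8.S rose by 0.50 ± 0.11 (0.0192) and hspa8.L by 0.42 (0.0386). hsp90ab1.S had 0.70 at day 11 (0.408). In the 4-day comparison chaperones (adjusted p = 0.000468) and the unfolded protein response (0.00522) were higher (adjusted p = 0.629 with an estimated correlation for each). Leaving out day 1 lost the slope calls of hspa5.S (0.141), xbp1.S (0.508) and hspa8.S (0.379), day 7 those of hspa5.S (0.0968), xbp1.S (0.0640), hspa8.S (0.0591) and hspa8.L (0.0971), day 11 those of hspa5.S (0.201), hspa8.S (0.114) and hspa8.L (0.451). Those of hspa5.L, cryab.S and cryab.L held with any 1 day left out.

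Regeneration-associated genes rose as a group of unequal members. Of 40 members 8 rose and 3 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.00323, and 0.288 without day 1; adjusted p = 0.628 with an estimated correlation). Medians were 0.08, 0.65, 1.88 and 1.35. tubb6.L, a beta-tubulin, rose by 1.71 ± 0.18 (adjusted p = 0.00285), sox11.S by 0.77 ± 0.12 (0.00519), sox11.L by 0.71 ± 0.11 (0.00638), jun.S by 0.71 ± 0.18 (0.0299) and socs3.L by 1.69 ± 0.36 (0.0346). marcksl1.L fell by 0.84 ± 0.13 (0.00632). The abundant growth cone genes basp1.S (-0.85 at day 11, 0.260), basp1.L (-0.85, 0.160) and marcks.S (0.00, 0.789) did not pass. Over the 4 days the list was higher (adjusted p = 0.000265; adjusted p = 0.629 with an estimated correlation). socs3.S was called and, adjusted over the list alone, 17 were higher and 2 lower. Tubulin, actin and growth cone cytoskeleton genes (39) had 8 risen and 1 fallen (12 and 1 adjusted over the list alone; camera adjusted p = 0.00919, and 0.439 without day 11; adjusted p = 0.725 with an estimated correlation). tuba1b.S rose by 0.70 ± 0.14 (0.0146) and tubb2b.S by 0.57 ± 0.14 (0.0244), while tubb4a.1 had -0.72 at day 11 (0.366). With .L and .S copies summed the list had an adjusted p of 0.126. Slope calls were lost without day 1 for sox11.S (0.0560), sox11.L (0.0876), jun.S (0.984) and socs3.L (0.317), without day 7 for jun.S (0.0683) and socs3.L (0.334), without day 11 for socs3.L (0.116), tuba1b.S (0.159) and tubb2b.S (0.301). Those of tubb6.L and marcksl1.L held with any 1 day left out.

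AP-1 and immediate early genes had their highest median at day 3. Medians of the 30 members were 0.45, 2.38, 1.04 and 0.07 (below 0 at day 11 with total counts). The list was higher over the 4 days (camera adjusted p = 0.000382; adjusted p = 0.629 with an estimated correlation). fosl1.L was called, and 14 were higher adjusted over the list alone. atf3.L had log2 ratios of 1.63, 5.95, 6.44 and 5.68 (adjusted p = 0.00128 without day 1), jun.L 1.75, 5.27, 5.07 and 4.73 (0.00148), junb.L 1.49, 3.93, 3.48 and 2.45 (0.00799) and jund.S, the most abundant, 0.62, 2.88, 2.15 and 1.83 (0.0163). With day, fos.L fell by 1.69 ± 0.29 (0.0127) and nr4a1.L by 1.03 ± 0.24 (0.0234), while jun.S rose, as 2 fallen and 1 risen also over the list alone. The list's slope had an adjusted p of 0.920. It fell without day 1 (2.59e-06) and rose without day 11 (0.0369). Leaving out day 1 lost the slope calls of jun.S (0.984), day 7 those of fos.L (0.0792) and jun.S (0.0683), day 11 those of fos.L (0.124) and nr4a1.L (0.187).

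The cytokine, apoptosis and DLK-JNK lists were higher over the 4 days in camera, the last with members of both directions. JAK-STAT and cytokine signalling genes (22) were higher over the 4 days (camera adjusted p = 0.000578; adjusted p = 0.629 with an estimated correlation). socs3.S was called, and 7 were higher adjusted over the list alone. With day 4 rose, also over the list alone, among them cish.L by 1.23 ± 0.18 (adjusted p = 0.00447), pim1.S by 0.97 ± 0.20 (0.0181) and pim1.L by 0.88 ± 0.18 (0.0146). The list's slope had an adjusted p of 0.326. Apoptosis genes (12) were higher over the 4 days (camera adjusted p = 0.0164; adjusted p = 0.629 with an estimated correlation). They rose with day (0.0164, and 0.130 without day 1; adjusted p = 0.628 with an estimated correlation), with 3 risen and 0 fallen, also over the list alone. casp9.S rose by 0.65 ± 0.11 (0.00766). mcl1.L, which opposes apoptosis, had 1.59, 1.10 and 0.58 at days 3, 7 and 11 (adjusted p of the slope 0.777). DLK-JNK pathway genes (27) were higher over the 4 days (adjusted p = 0.0427, 0.299 without day 3, 0.0626 with copies summed, adjusted p = 0.629 with an estimated correlation). 5 members were higher adjusted over the list alone, and 0 over all genes. Medians of the DLK-JNK list were 0.75, 0.42 and 0.33 at days 3, 7 and 11. Members over 2-fold higher and lower numbered 10 and 0 at day 3, 8 and 6 at day 7, and 4 and 7 at day 11. gadd45g.L rose by 1.11 ± 0.22 (0.0167) and gadd45a.L by 0.94 ± 0.22 (0.0249), as the 2 risen of the list against 3 fallen (2 and 5 adjusted over the list alone). The 3 fallen were dusp4.L (0.0107), map2k7.S (0.0300) and dusp6.L (0.0476). The list's slope, at an adjusted p of 0.961, was reversed, to a fall, without day 1 (0.00761). Slope calls were lost without day 1 for pim1.S (0.552), pim1.L (0.583), gadd45g.L (0.353) and gadd45a.L (0.414). Leaving out day 7 lost those of map2k7.S (0.104) and dusp6.L (0.110), day 11 those of casp9.S (0.0653), dusp4.L (0.104), map2k7.S (0.132) and dusp6.L (0.315). That of cish.L held with any 1 day left out.

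Metabolic lists moved unevenly. Cholesterol synthesis genes (22) were higher over the 4 days (camera adjusted p = 0.00269, 0.0525 without day 11, adjusted p = 0.629 with an estimated correlation). Medians were 0.67, -0.35, 0.39 and 1.49, and 0.34 for sham. 1 member rose with day, also over the list alone, acat2.S by 0.73 ± 0.14 (adjusted p = 0.0112), and fdps.L had 3.59 at day 11 (0.376). The list's slope had an adjusted p of 0.0839 (rising at 1.89e-07 without day 1 and 0.0202 without day 7). Mitochondrial respiratory chain genes (92) had medians of -0.17, -0.59, 0.03 and 0.39 (below 0 at day 7 with total counts). 4 rose and 0 fell (0 adjusted over the list alone; camera adjusted p = 0.000129, and 0.256 without day 11; adjusted p = 0.737 with an estimated correlation), and the 4-day value, whose direction is lower, was 0.220 (0.000529 without day 11). atp5b.S, their most abundant member, had 0.05 at day 11 (0.878). Glycolysis (14 members, 2 risen, 2 over the list alone) had a slope adjusted p of 0.506, with tpi1.L at 0.54 on day 11 (0.458). Polyamine and arginine genes (15) had 4 risen and 1 fallen, also over the list alone, and an adjusted p of 0.163. odc1.L, ornithine decarboxylase, rose by 0.97 ± 0.11 (0.00311), smox.L by 1.03 ± 0.16 (0.00575), smox.S by 0.79 ± 0.14 (0.00803) and arg2.S by 0.87 ± 0.22 (0.0424). oaz1.L had -0.47 at day 11 (0.498). Leaving out day 1 lost the slope calls of smox.S (0.180) and arg2.S (0.945), day 7 those of arg2.S (0.111), day 11 those of acat2.S (0.146). Those of odc1.L and smox.L held with any 1 day left out.

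The remaining lists did not pass as lists for the slope. Neurotrophic and growth factor signalling (32 members, 1 risen and 4 fallen, 1 and 5 adjusted over the list alone) had an adjusted p of 0.428. gfra2.L, a GDNF-family receptor, rose by 1.14 ± 0.11 (adjusted p = 0.00279). gfra2.S fell by 0.89 ± 0.20 (0.0193), fgf9.L by 0.87 ± 0.11 (0.00375), igfbp2.L by 1.25 ± 0.20 (0.00632) and bdnf.L by 0.52 ± 0.13 (0.0275). igf2.L and igf2.S had 5.47 and 4.80 at day 3 (adjusted p = 0.00573 and 0.00194 without day 1). KLF factors (21, 1 risen and 2 fallen, 2 and 3 over the list alone) had an adjusted p of 0.326. klf12.L fell by 0.80 ± 0.15 (0.0111), and klf6.L was at 1.87 on day 7 (0.0176 without day 1). Matrix and matrix protease genes (31, 3 risen and 3 fallen) had 0.879. mmp24.L rose by 0.99 ± 0.14 (0.00460), mmp24.S by 0.66 (0.00817) and fn1.L by 0.91 ± 0.21 (0.0218), and mmp17.L fell by 0.55 ± 0.11 (0.0126). Complement and interferon genes (9, 0 called) had 1.68 at day 3, an adjusted p of 0.326 (falling at 0.00973 without day 1) and a 4-day value of 0.117 (higher at 0.00853 without day 11). Cell cycle genes (28, 0 called) had 0.506 and axonal transport genes (22, 0 called) 0.466, with kif5a.S, dctn1.L and dync1h1.L at -0.01, 0.07 and 0.59 on day 11. Slope calls were lost without day 1 for fn1.L (0.284) and mmp17.L (0.158), without day 7 for bdnf.L (0.0749) and fn1.L (0.0729), without day 11 for gfra2.S (0.147), bdnf.L (0.320), fn1.L (0.0811) and mmp17.L (0.0849). Those of gfra2.L, fgf9.L, igfbp2.L, klf12.L, mmp24.L and mmp24.S held with any 1 day left out.

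**Figure D3:**
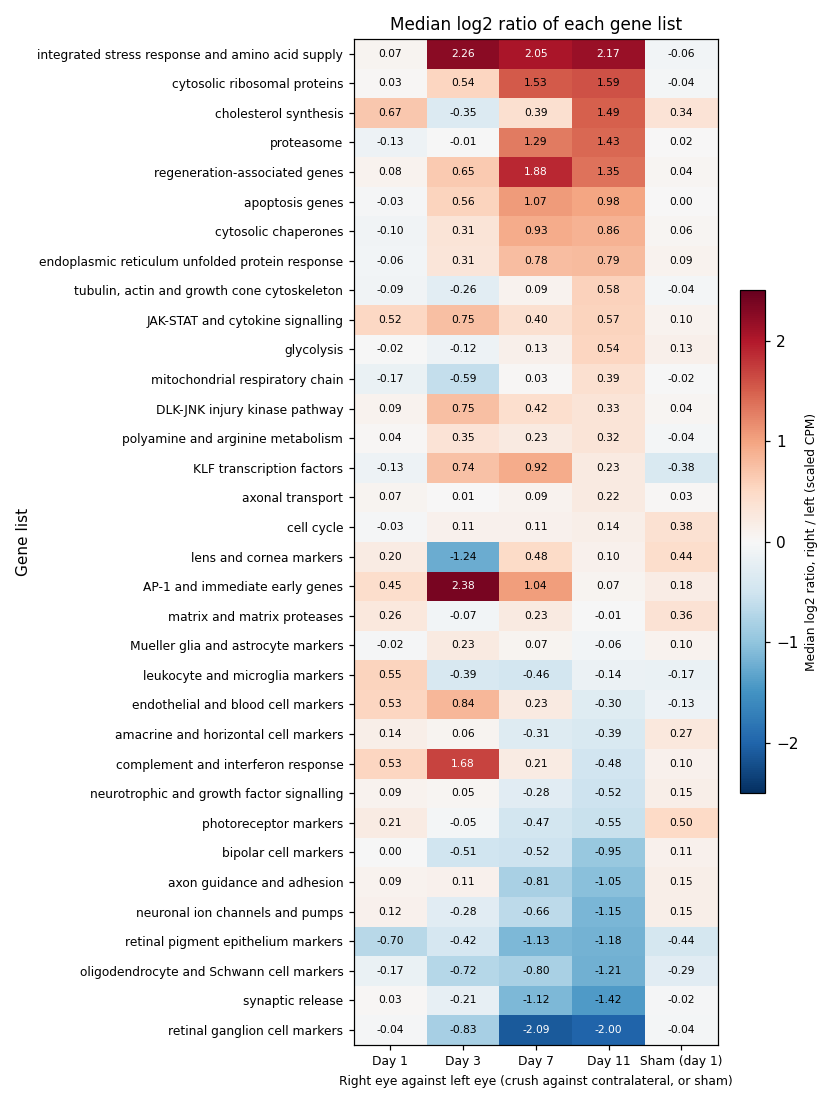
Median log2 ratio of the right over the left eye for the 34 gene lists (vertical) after crush at days 1, 3, 7 and 11 and after sham surgery (horizontal), red above and blue below 0. Retinal ganglion cell markers reached -2.00 and ribosomal proteins 1.59 at day 11, while some smaller medians, such as 0.09 for the cytoskeleton at day 7 and 0.07 for AP-1 genes at day 11, change sign with total counts.

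In camera, 11 lists were higher and 4 lower over the 4 days, and 9 rose and 6 fell with day, the latter in a test of lists that was not planned. With an estimated correlation, and with fry, 0 of the 34 lists passed in either test. The loss cannot be read as an effect of correlation alone, since lists with an estimate below the preset 0.01 lost their slope calls too. Regeneration-associated genes, with an estimate of 0.0086, went from a camera adjusted p of 0.00323 to 0.628. Apoptosis genes, at -0.021, went from 0.0164 to 0.628. With so few residual degrees of freedom, that setting cannot decide whether correlation accounts for the calls.

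Single days add genes whose ratios were not tested. At day 1 the highest were ahnak-like.S (9.23-fold), the sterol synthesis gene msmo1.1 (7.20-fold), fbn3.L (6.64-fold) and cenpi.L (4.69-fold). The lowest were foxj1.2.S (4.50-fold lower), the Wnt antagonist sfrp1.S (4.41-fold), rnf180.1 (4.01-fold) and casp1.L (3.94-fold). At day 3 the highest were the kinase gene map3k14.S (at least 166-fold), flnc.L (172-fold, counting interval 66.6 to 634), the leptin receptor gene lepr.L (135-fold) and the leptin gene lep.S (117-fold, 0.668 to 78.5 CPM). hcn2.L was 17.2-fold, hapln4.L 11.6-fold, bmp2.S 7.35-fold and nrm.L 7.18-fold lower. At day 7 the highest were btg5.L (648-fold, 179 to 5350, with 2 counts in the contralateral eye), c14orf79.L (584-fold, 105 to 23097, with 1 count), medag.S (529-fold, from 94.9, with 1 count) and the protease gene mmp28.S (at least 109.8-fold). The lowest were aox1.L (at least 228-fold lower), hapln4.L (at least 214-fold, a perineuronal net linker), grp.S (149-fold) and fxyd7.L (126-fold). At day 11 lep.L was at least 727-fold higher, upp2.L 295-fold, lepr.L 244-fold and medag.S 198-fold. The potassium channel gene kcnf1.L was 411-fold lower (87.0 to 0.212 CPM), with hapln4.L at least 149-fold, aox1.L at least 144-fold and kcnip3.S at least 113-fold lower.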

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

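The tests on the fall of ganglion cell markers, on vim.L and cd44.S, and on other splits for the genes of the 4-day comparison were chosen only after the result was seen, thinning was added once the data had been seen but before its own value was, and the other tests were written before their own values were seen.

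Retinal ganglion cell markers fell with day (camera adjusted p = 2.11e-09; 0.628 with an estimated correlation), with pou4f3.L at a slope of -1.86 and medians near -2 at days 7 and 11. If RNA of other retinal cells had diluted the later crush libraries, markers of those cells would lie above 0, yet the photoreceptor median at day 11 was -0.55 (camera slope adjusted p = 5.50e-06). Between the sham eyes that median was 0.50, so that a shift of this size also arose without crush. Bipolar cell markers also fell (0.0259, and 0.165 without day 1). With an estimated correlation the slopes of these 2 lists had an adjusted p of 0.628 each. Not all such lists lay below 0: medians at days 7 and 11 were 0.07 and -0.06 for Mueller glia and astrocytes (upper quartile 1.06 at day 11), 0.23 and -0.30 for endothelial and blood cells and 0.48 and 0.10 for lens and cornea. The values thus argue against RNA of the other retinal cells as a whole as the cause of a median fall near 2, and do not exclude a smaller share of glial, vessel or lens RNA. The fall was not removed by another scaling: the highest median at days 7 and 11 with total counts or RLE factors was -1.96. A lower level of these transcripts on tagged ribosomes is therefore consistent with the tests, as a hypothesis found and tested on the same data. Loss of ganglion cells, lower transcription and lower ribosome loading of these genes were not told apart by any test run here.

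Ribosomal protein (camera adjusted p = 5.31e-21) and proteasome genes (2.21e-15) rose with day, with an adjusted p of 0.628 for each under an estimated correlation, and ribosomal protein genes are short. Against lists matched on length and expression both medians at day 11 still lay at percentile 100, with 1.59 for ribosomal proteins against 0.72 for the median matched list. Members of matched lists were drawn independently, so this percentile takes no account of correlation within a list. The draws could also include the list's own genes, so a matched median is not a background of length and expression alone. Mitochondrial respiratory chain genes, which are about as short, had 0.39 against 0.44. Depth differed most between the eyes at day 7, and after thinning every library to the smallest total the ribosomal protein median of that day was 1.47. A biological rise may therefore be considered as a hypothesis, with RNA quality and antibody yield not tested.

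The vim.L and cd44.S ratios could come from glial or immune RNA in the later crush libraries. The other Mueller glia markers had an upper quartile of 0.60 at day 11, below the log2 ratio of 1 set for that explanation. Of all 25 glial markers, 7 were over 2-fold higher and 7 over 2-fold lower at day 11. The limit concerns the other markers as a set, so it cannot exclude glial RNA in which vim.L and cd44.S rose without them. For leukocytes the upper quartile was 1.63 and the median -0.14, from 11 markers of which most have few CPM. RNA of glia, RNA of leukocytes and expression in ganglion cells therefore cannot be told apart here.

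The crush effect changed with day for 3296 genes, and 1 of 24 orders of the days, the real one, gave as many. The highest other order, which exchanges days 7 and 11, gave 1960, and the reverse order 1531. A share of 1 of 24 is under 0.05, but it is the smallest that 24 orders can reach. With 1 library per eye and day, it does not exclude chance. For gene lists the real order gave 15, and 5 of 24 orders gave as many, with up to 17 in another, so chance is not excluded for that count. The list slopes with an adjusted p under the threshold are those above and regeneration-associated genes (0.00323, and 0.288 without day 1), the growth cone cytoskeleton (0.00919, and 0.439 without day 11), the integrated stress response (1.82e-07, reversed at 0.331 without day 1), apoptosis genes (0.0164, and 0.130 without day 1), the mitochondrial respiratory chain (0.000129, and 0.256 without day 11), cytosolic chaperones (6.05e-06), the unfolded protein response (0.000242), synaptic release (0.000777), ion channels (0.0152) and axon guidance (0.00251). With an estimated correlation 0 of the 34 lists passed, and these 10 had adjusted p values from 0.628 to 0.737. The named genes whose slope passed besides pou4f3.L were anxa2.S (1.56), Xelaev18024621m (1.32), Xelaev18016849m (1.49), phyhip.L (1.28), cars.S (1.22), cpne7.S (-1.69), Xelaev18036861m (-1.67), MGC145303.L (-1.71) and prrt1.L (-1.16).

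For the 4-day comparison, 8 splits of the 8 libraries part all 4 pairs, which is too few for a share under 0.05. The real split gave 10 genes and the highest other 1, and 1 of 8 splits gave as many. For lists the real split gave 15 and the highest other 14, again 1 of 8. The split that sets the crush libraries of days 7 and 11 against their contralateral libraries, with both day 1 libraries on 1 side and both day 3 libraries on the other, called 8341 genes, which points to a structure of the samples, the difference between the eyes at days 7 and 11.

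In 2 of 64 sets of 4 per-day values, 1 day stood apart from the other 3, where chance alone gives about 1 in 20. Both times it was day 1: for pmel-like.S (gap over range 0.907) and for the median of the integrated stress response list (0.902).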

How the results depend on the processing

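Settings for the slope other than day, voom, RLE and leave-one-out, and all thinned libraries, were added after the data had been seen. Pseudocounts were not run, since the tables hold counts. Where a value below differs from that in the report, the cause was not tested unless stated.

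The 4-day count of 10 genes became 0 without the day block, 3127 in DESeq2, 25 with no filter (more genes tested), 1 with 100 counts in each of 4 libraries (1 of the 10 genes passed that filter, and it stayed called), 3956 with 7 uninjured controls (more libraries, without the day term), and 0 to 2678 with 1 day left out. It was 10 with RLE (10 shared) and with a 2-fold minimum, 12 in voom (6 shared), 8 with summed copies (3 of the 10 tested, 3 shared) and 8 after thinning (7 tested, 6 shared). The slope count of 3296 ranged from 1233 to 5163 with 1 day left out, and was 2744 on day (2325 shared), 4672 in voom (3225 shared), 3398 with RLE, 3283 thinned, 2815 without the block and 2635 with copies summed.

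The lists called, 15 in each test, were 0 with an estimated correlation and 0 with fry in both tests, and 13 to 17 in all other settings run. Without day 1, 3 slopes reversed: AP-1 genes (2.59e-06; 2.59e-06 to 0.865 with 1 day left out), the integrated stress response (0.331; 2.64e-12 to 0.331) and the DLK-JNK pathway (0.00761; 0.00761 to 0.738).

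Genes over 2-fold changed in number with the count minimum, which also sets how many genes are counted: with 50 counts there were 1750 at day 1, 4132 at day 3 and 1414 for sham, and with 1000 counts 26, 1079, 3872 and 4601 at days 1, 3, 7 and 11, 3 for sham and 4397 for naive TRAP against total retina. At 4-fold, a stricter limit, they were 15, 430, 2102 and 2494, with 12 for sham and 2552 for TRAP.

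The slopes of the 10 genes named by smallest p kept their calls in all settings run for them. Of 235 list members called for the slope, 69 to 234 stayed called with 1 day left out. Depth limits the ratios of genes near 0 counts, such as btg5.L and medag.S.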

Other observations

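The tests of symbol families were chosen only after the result was seen, while the test of gene copies was written before its own value was seen.

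Families of genes that share a symbol stem gave adhesion genes that no list above covers. Of 192 families, cadherins (cdh) had 11 of 29 members fallen with day in edgeR and none risen (camera adjusted p = 3.89e-06, median log2 ratio -1.83 at day 11), the neuronal adhesion family slitrk 7 of 12 fallen (4.21e-05, -2.62), protocadherins (pcdh) 9 of 20 fallen and 1 risen (0.000155, -1.34) and the Iroquois factors irx 6 of 11 fallen (0.00143, -2.27). Among rising families were tRNA synthetases, 17 of 22 risen (1.41e-09, 1.97), and translation initiation factors (eif), 15 of 60 risen (1.30e-07, 1.02). All of these had an adjusted p of 0.781 with an estimated correlation. The irx and tRNA synthetase families share members with lists above. Examples are irx2.L and irx3.L of the ganglion cell markers, and gars.L and sars.L of the stress response list.

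The .L and .S copies of a gene might have drifted apart in their response to crush. Of 4781 pairs with both copies tested, 214 had a slope of the L minus S difference past an adjusted p of 0.05 in limma, or 4.48% (962 at an unadjusted p under 0.05), against the 1% set as the minimum for this hypothesis. Across pairs the log2 ratios of the copies correlated at r = 0.561 at day 7 and 0.584 at day 11, against 0.0415 for sham. At day 11, 111 pairs had both copies over 2-fold in opposite directions, and of 347 pairs with both copies called in the slope test 2 went in opposite directions. In rgs8 the .L copy had log2 ratios of 1.42 and 1.30 at days 7 and 11 and the .S copy -1.38 and -2.31 (adjusted p of the difference 0.00174). In gfra2 they were 3.31 and 3.89 against -2.00 and -3.06 (0.00227). Reads shared between near-identical copies pull their ratios together, so such differences may be underestimated, and this was not tested.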
